A study of Mus musculus with 161 samples.

How the data were processed

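The series profiled mRNA of single mouse cells captured on the Fluidigm C1 microfluidic system, in which each library comes from 1 capture site. The labels give 161 libraries from C57BL/6 mice in 3 sorted populations: 66 common monocyte progenitors (cMoP) of the bone marrow, 57 bone marrow (BM) monocytes and 38 blood monocytes. The groups were taken from the labels alone. No label names an animal, so cells were not treated as replicates and each group counted as 1 sample. No significance test between groups was run, and no p-value, standard error or number of changed genes is given. A bootstrap range over pairs of cells and random sets of libraries, used below, cover the spread between cells only.

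The deposited values are TPM, the abundance of a transcript scaled to a fixed total per cell, with 1 column per cell, and per the submitters' processing notes they were made with RSEM 1.2.19 on the mouse build GRCm38. The aligner, its settings and the gene annotation are not given in the sources used here. The table holds 43280 gene symbols, of which 18780 are listed at 0 in every cell. Column sums ran from 997939 to 999955 TPM, 40 rows hold values with more than 2 decimals, and 0 columns were left without a matching library. TPM keeps no read depth, so the depth per cell is unknown, and the number of genes above 1 TPM served as the measure of library complexity. TPM values sum to a fixed total, so a very abundant transcript lowers the values of all others in that cell. An exact 0 can be a failed estimate or a transcript lost in capture: S100a9 is listed at 0 in all 161 cells.

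The effect size was the difference between 2 groups in the mean over cells of log2(TPM + 1), later stage minus earlier, with the SD over cells of each group. The pseudocount of 1 understates differences of genes with low values. Shares of cells above 1 TPM carry 95% exact (Clopper-Pearson) binomial intervals, which cover the counting of cells only. For 0 cells the limit given is that of 3 cells of the total.

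The genes named were chosen by a rule fixed before the data were examined. It takes Ms4a3 and the genes of the sort gates (Kit, Csf1r, Flt3, Ly6c2 and Itgam). It takes the 10 largest differences in each direction for BM monocytes against cMoP and for blood against BM monocytes, and the 5 largest for blood monocytes against cMoP. Such a gene had to lie above 1 TPM in at least 50% of the cells of the higher group. Symbols of predicted genes, mitochondrial genes, ribosomal proteins and microRNAs were left out there. Of each gene list described, up to 4 measured members with the largest absolute difference could be named. Genes named outside the rule are marked where they appear.

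31 gene lists were fixed at the same time. They cover the gate, the MS4A family, primary granules, neutrophil secondary granules and maturation, stem and multipotent progenitors, S phase, G2 and M phase, classical monocytes, Ly6C-low monocytes, MHC class II presentation, conventional and plasmacytoid dendritic cells, myeloid transcription factors, the type I interferon response, immediate early and stress genes, ribosome biogenesis, ribosomal proteins, nuclear and mitochondrial oxidative phosphorylation genes, glycolysis, migration and adhesion receptors, pattern recognition and inflammatory signalling, and lysosome and phagocytosis. The rest are markers of B cells, T cells, NK cells, erythroid cells, basophils and mast cells, eosinophils, megakaryocytes and platelets, and macrophages. A member counted as measured when above 1 TPM in at least 10% of the cells of any group, which 14003 genes passed. For each list with at least 3 measured members, the median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test.

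Each cell was also assigned to the nearest group mean by Pearson correlation over measured genes, left out of its own group's mean. The functions for differences and list percentiles were tested on simulated data, resampled from the earlier group of each comparison over 43280 genes with 200 genes multiplied or divided by a known factor. The changed genes were drawn from those above 1 TPM in at least 50% of the earlier group's cells. Each gene was resampled on its own, so the simulation held no gap in genes per cell between groups. For BM monocytes against cMoP, 96% of the genes changed 2-fold and 100% of those changed 4-fold had the right sign. Sizes came back smaller, with a median log2 size of 2.96 there for genes changed 16-fold. For blood against BM monocytes the shares with the right sign were 82% and 98%, and for blood monocytes against cMoP 94% and 98%.

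The flow cell and lane in the labels separate 60 of the cMoP libraries from both monocyte populations, and 6 cMoP libraries carry no flow cell in their label. The cMoP and the monocytes can therefore not be told apart from their flow cells, while BM and blood monocytes share flow cell and lane. The alternatives tried were other detection thresholds and pseudocounts, the log2 ratio of mean TPM, median-ratio scaling, TPM rescaled without mitochondrial and ribosomal rows, other filters on low values, a filter on genes per cell, Spearman correlation, and a set of cells without the 6 libraries. A planned set matched on the number of genes held no cell and was not run. 3 sets of cells were added after seeing the data. One is without the libraries with over 15% of TPM in mitochondrial rows or under 2% in ribosomal protein rows, and 1 is cells with 4500 to 6000 genes above 1 TPM. The last combines both, and was added because the 4500 to 6000 range had turned the sign of the oxidative phosphorylation list. For 1 list, blood and BM monocytes were also paired within 100 genes above 1 TPM, with a range from 1000 bootstraps over pairs, after seeing the data. The symbols were matched to GENCODE release M21 on GRCm38, where 39469 of them were found. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.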

Results

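Single-cell mRNA profiles were recorded from 66 cMoP, 57 BM monocytes and 38 blood monocytes of C57BL/6 mice. The cMoP is a proliferating bone marrow progenitor committed to the monocyte lineage, sorted as lineage-negative CD117+ CD115+ CD135- Ly6C+ cells. BM monocytes were sorted by the same gate but without CD117, and blood monocytes as CD115+ CD11b+ cells with high Ly6C. The series concerns the expression history of Ms4a3, a membrane protein gene of the MS4A family, as a trace of monocyte origin, so the comparisons follow Ms4a3 and the transcriptome along these stages. Each group is 1 sample of cells, so no difference has a replicate check.

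Median numbers of genes above 1 TPM were 6661.5 in cMoP, 4719 in BM monocytes and 4319.5 in blood monocytes. Mitochondrial transcripts made up a median of 7.08% of TPM in cMoP, 4.25% in BM monocytes and 4.65% in blood monocytes. 11 cMoP libraries had between 16.6% and 47.7% of TPM in mitochondrial rows, against at most 11.1% in the other 55. 1 blood library had 0.965% of TPM in ribosomal protein rows. The 6 cMoP libraries without a flow cell in their label held 8720 to 9971 genes above 1 TPM, and the other 60 at most 7552.

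**Figure D1:**
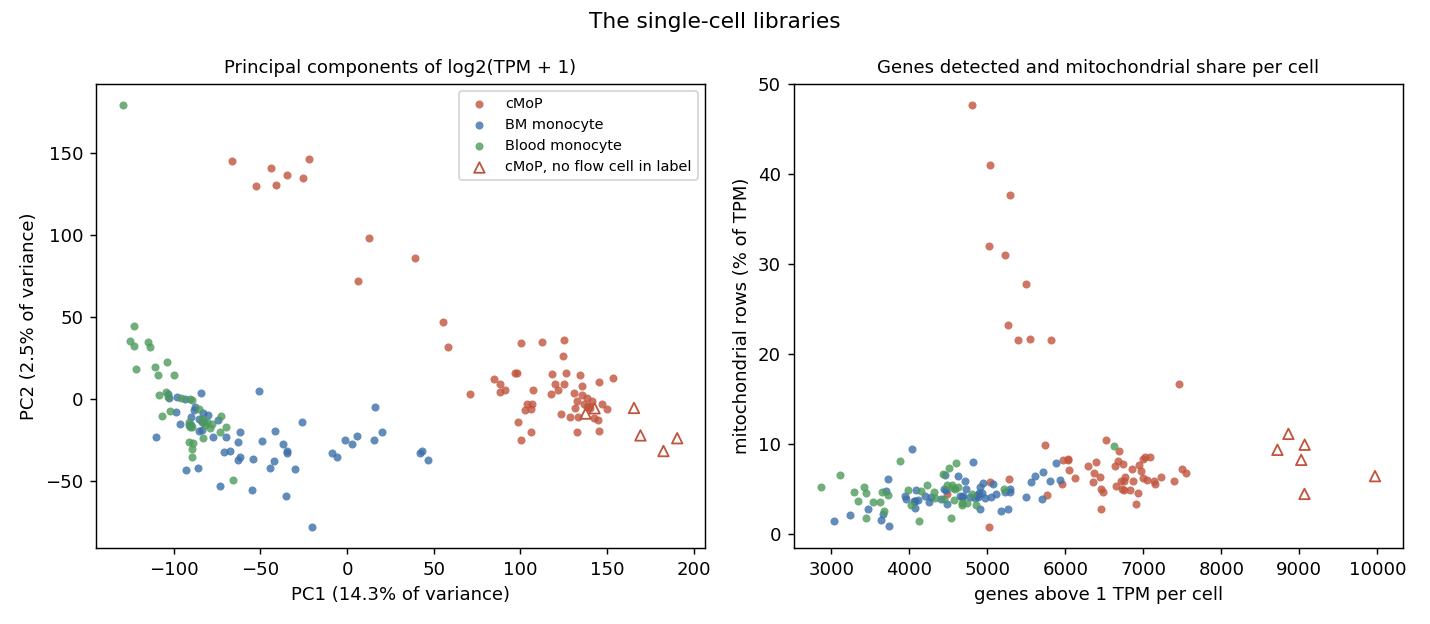
Left, the first 2 principal components of log2(TPM + 1) for all cells, coloured by sorted population, with open triangles for the 6 cMoP libraries that have no flow cell in their label. Right, genes above 1 TPM against the percent of TPM in mitochondrial rows per cell. The first component held 14.3% of the variance. Its median was 122.6 in cMoP, -62.7 in BM monocytes and -90.8 in blood monocytes. Flow cell and lane also separate cMoP from the monocytes.

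Ms4a3 was abundant in the progenitor and close to absent from the values of both monocyte populations. It lay above 1 TPM in 66 of 66 cMoP (100%, 95% interval 94.6 to 100%), in 4 of 57 BM monocytes (7.02%, 1.95 to 17.004%) and in 4 of 38 blood monocytes (10.5%, 2.94 to 24.8%). Mean Ms4a3 was 627 TPM in cMoP, 0.412 TPM in BM monocytes and 0.456 TPM in blood monocytes. On the log2 scale the cMoP had a mean of 8.29 ± 2.36 (SD over 66 cells), BM monocytes 0.19 ± 0.71 and blood monocytes 0.24 ± 0.74. The highest single value was 8.29 TPM among BM monocytes and 6.65 TPM among blood monocytes. Above 10 TPM, Ms4a3 was listed in 90.9% of cMoP, in 0 of 57 BM monocytes, which allows a share of up to 5.26% (3 cells of the total), and in 0 of 38 blood monocytes, which allows up to 7.89%. The low values in monocytes were in the range of Ms4a1, a B cell gene of the same family, which lay above 1 TPM in 28.1% of BM monocytes and 36.8% of blood monocytes at means of 0.892 and 1.73 TPM. Ms4a3 lies on chromosome 19 from 11629496 to 11640851 on the minus strand of GRCm38 and is annotated as protein-coding.

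Other MS4A genes had the opposite pattern. Of 11 measured family members, 9 were higher in BM monocytes than in cMoP and 2 were lower, with a median difference of 1.17 (percentile 100 of the matched random lists). Ms4a4c differed by 6.08, from a mean of 59.6 TPM in cMoP to 1261 TPM in BM monocytes. Ms4a4a differed by 5.38, and Ms4a6b by 3.09. Between BM and blood monocytes the family had no common direction, with 4 members higher and 7 lower in blood and a median of -0.10, which was 0.40 as the log2 ratio of mean TPM.

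The genes of the sort gates gave a check of the labels. Kit, which encodes CD117, lay above 1 TPM in 59.1% of cMoP (46.3 to 71.0%), in 0 of 57 BM monocytes and in 0 of 38 blood monocytes. Csf1r, which encodes CD115, lay above 1 TPM in 84.8%, 80.7% and 94.7% of the cells, and Ly6c2 in 100% of each group. Above 10 TPM, Ly6c2 was listed in 100% of cMoP and of BM monocytes, but in 35 of 38 blood monocytes (92.1%). Its SD on the log2 scale was 3.33 in blood monocytes, against 1.32 in cMoP and 1.55 in BM monocytes. Flt3, which encodes CD135, lay above 1 TPM in 30.3% of cMoP, 33.3% of BM monocytes and 31.6% of blood monocytes. Most of these values were low, as Flt3 lay above 10 TPM in 7.58%, 0% and 5.26% of the cells. Itgam, which encodes CD11b, differed by 2.95 between BM monocytes and cMoP and by 0.41 between blood and BM monocytes. Over the 5 genes of the gate list the median difference was 0.10 for BM monocytes against cMoP, and it was -0.08 under median-ratio scaling.

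From cMoP to BM monocytes, primary granule and S phase genes were lower and monocyte effector genes higher. Mpo, the myeloperoxidase of primary granules, had a mean of 10734 TPM in cMoP and 1.603 TPM in BM monocytes, a log2 difference of -12.90. The serine proteases of the same granules followed, with -10.15 for Elane, -8.97 for Ctsg and -8.83 for Prtn3. In the other direction, the chemokine gene Ccl6 was higher by 8.46, at 2164 TPM in BM monocytes and 24.5 TPM in cMoP. Lyz2, which encodes lysozyme, was at 51588 TPM in BM monocytes and 1064 TPM in cMoP, a difference of 6.42.

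Of 10 measured primary granule genes, 9 were lower in BM monocytes and the median difference was -6.18 (percentile 0). Elane was still above 1 TPM in 19.3% of BM monocytes (10.0 to 31.9%), Prtn3 in 28.1% (16.97 to 41.5%) and Ctsg in 12.3% (5.08 to 23.7%), while Mpo was in 3.51% (0.428 to 12.1%). After these and Ms4a3, the other 5 of the 10 genes with the largest negative differences were the protease inhibitor gene Cst7 at -6.72, the serine synthesis gene Phgdh at -6.39, the nucleolar gene Nop58 at -6.27, Cdca7 at -6.17 and the cyclin-dependent kinase gene Cdk6 at -6.09.

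All 30 measured S phase genes were lower in BM monocytes, with a median of -4.44 (percentile 0). Tipin differed by -5.89, Rrm2, a subunit of ribonucleotide reductase, by -5.85 and Mcm3, a part of the replicative helicase, by -5.71. All 35 G2 and M phase genes were lower as well, with a median of -2.15 (percentile 0.01). As the log2 ratio of mean TPM these medians were -2.28 and -0.60, and among cells with 4500 to 6000 genes, without libraries of high mitochondrial or low ribosomal share, -4.04 and -0.12. The last lies at percentile 76.5 of the matched random lists, so the G2 and M phase list did not stand apart in that range. Top2a, a topoisomerase of dividing cells, had a mean of 606 TPM in cMoP and 206 TPM in BM monocytes, and lay above 10 TPM in 95.5% and 31.6% of the cells. All 30 ribosome biogenesis genes were lower, with a median of -3.14 (percentile 0) and -1.87 among cells with 4500 to 6000 genes. Nop56 and Gnl3 differed by -4.79 and -4.86. Stem and multipotent progenitor genes were lower in 14 of 14 cases, with a median of -1.01 (percentile 0.22), led after Cdk6 by Myb at -4.68 and Cd34 at -3.50.

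Of 27 classical monocyte genes, 24 were higher in BM monocytes, with a median of 1.94 (percentile 100). Fn1, the fibronectin gene, differed by 6.32, the chitinase-like gene Chil3 by 6.44 and the calcium-binding gene S100a6 by 6.43. The largest differences by size also held Wfdc17 at 7.44, the inhibitory receptor gene Lilrb4 at 7.21, Ifitm6 at 7.19, Clec4a3 at 6.53, Plbd1 at 6.52 and the galectin gene Lgals3 at 6.43. Of 30 type I interferon response genes, 28 were higher, with a median of 1.10 (percentile 100). Ifi27l2a led them at 7.80, and Irf7, a transcription factor of the interferon response, differed by 4.19. Immediate early and stress genes were higher in 18 of 23 cases, with a median of 1.21 and with Atf3 at 5.06, Btg2 at 4.90 and Fos at 3.99. Pattern recognition and inflammatory signalling genes were higher in 26 of 33 cases at a median of 0.73, and lysosome and phagocytosis genes in 15 of 23 at 0.75, led by Ctss at 4.86 and Cd68 at 4.84. Ly6C-low monocyte genes had a median of 0.40, with 16 of 21 higher, and myeloid transcription factors one of 0.42, with 16 of 25 higher, among them Id2 at 4.89. Myc went the other way at -4.95.

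Metabolic genes depended on the cells compared and on the scale. Nuclear oxidative phosphorylation genes had a median of -1.49 (percentile 0), with 72 of 76 lower in BM monocytes, but 0.79 among cells with 4500 to 6000 genes, where 10 of the 17 cMoP are libraries with a high mitochondrial share or few ribosomal transcripts. Without those libraries the median in the same range was -1.42 over 7 cMoP, and -2.04 over all other cells. As the log2 ratio of mean TPM over all cells it was -0.39. Glycolysis genes had a median of -0.87 (percentile 7.7) and ribosomal proteins one of -0.61 (percentile 7.195), which were 0.33 and 0.76 in the 4500 to 6000 range and -0.52 and -1.04 there without those libraries. All 13 mitochondrially encoded oxidative phosphorylation genes were lower, with a median of -1.94 (percentile 0.095), while the 11 cMoP libraries with over 15% mitochondrial TPM were part of the comparison; without them the median was -1.54 (percentile 11.8), and -0.55 in the range of 4500 to 6000 genes (percentile 51.5), so this list did not stand apart from random lists there. Ldha, the lactate dehydrogenase of glycolysis, differed by -4.25 and Sdha, a respiratory chain subunit, by -3.58.

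The remaining lists went both ways. MHC class II presentation genes had a median of -0.47 (percentile 46.1), which was 0.53 as the log2 ratio of mean TPM. Migration and adhesion receptors had a median of -0.28, with 12 of 25 higher, and 0.67 as the log2 ratio of mean TPM. Neutrophil secondary granule and maturation genes had a median of -0.02, with 5 of 10 higher, and 1.08 as the log2 ratio of mean TPM. Flow cell and lane differ between cMoP and BM monocytes, so this comparison cannot be told apart from them. The median over all 14003 measured genes was -0.45, and only 4 of the 20 genes named by size were also named from the log2 ratio of mean TPM.

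**Figure D2:**
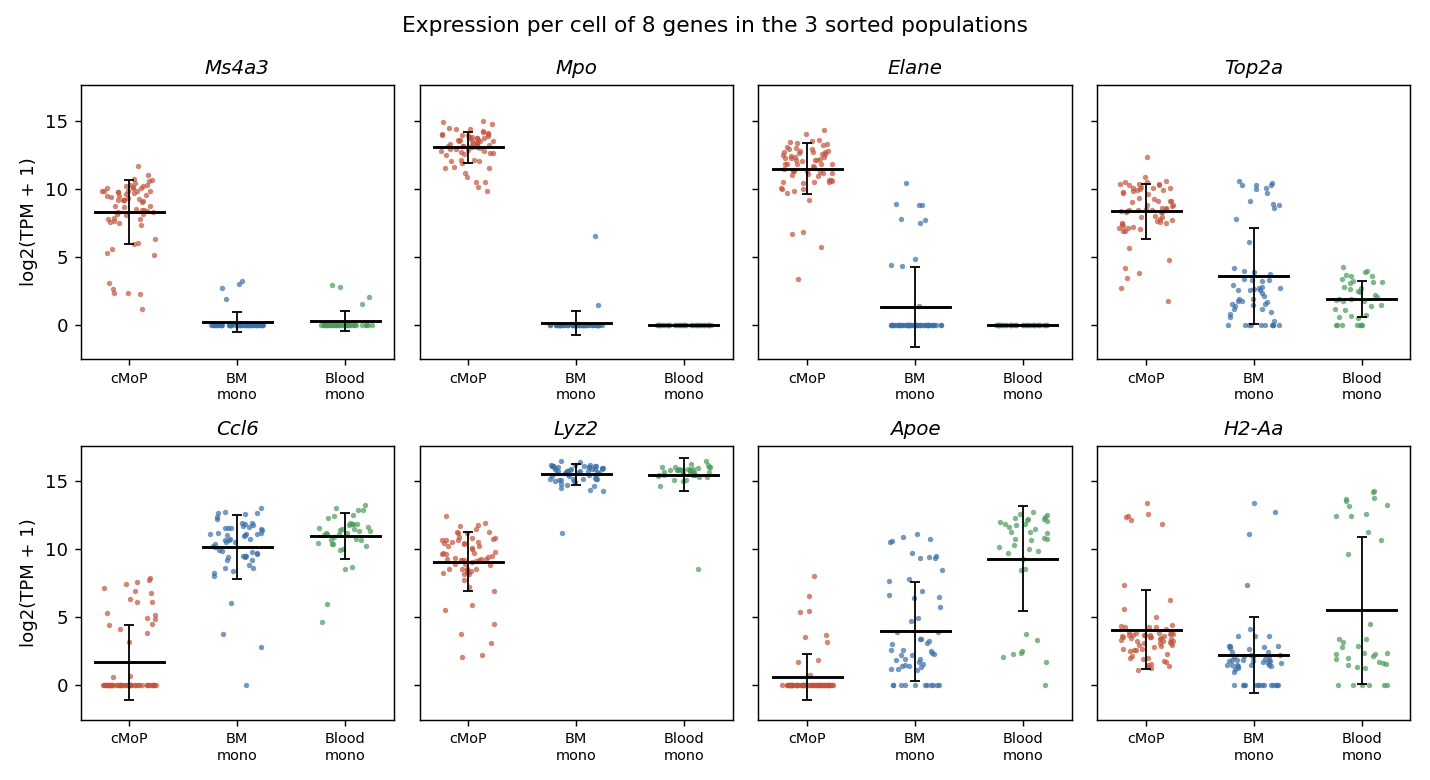
Expression per cell, as log2(TPM + 1), of 8 genes in cMoP, BM monocytes and blood monocytes; each point is 1 cell, the horizontal line is the mean and the bars are 1 SD over cells. Ms4a3, Mpo and Elane are at means of 8.29, 13.04 and 11.46 in cMoP and at 0.24, 0 and 0 in blood monocytes, while Ccl6 and Lyz2 are higher in both monocyte groups and Apoe is highest in blood.

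From BM to blood monocytes, the lipid carrier gene Apoe and antigen presentation genes were higher and genes of dividing cells lower. Apoe had a mean of 2375 TPM in blood monocytes and 243.7 TPM in BM monocytes, a log2 difference of 5.33. It lay above 1 TPM in 97.4% of blood monocytes (86.2 to 99.9%) and 80.7% of BM monocytes (68.1 to 89.95%). Above 10 TPM these shares were 81.6% and 38.6%, and the median over cells was 1804 TPM in blood and 4.91 TPM in BM monocytes. H2-Aa, an MHC class II chain, was higher by 3.27, and H2-Eb1 and Cd74 by 3.02 and 2.98. The membrane protein gene Plp2 had the largest negative difference, -5.70, with means of 37.2 TPM in blood and 628 TPM in bone marrow.

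Of 12 MHC class II presentation genes, 9 were higher in blood, 2 were lower and the median was 0.76 (percentile 100). The cells of the blood group varied widely for these genes, with an SD of 5.40 for H2-Aa and 4.89 for Cd74 on the log2 scale. In this comparison the B cell list had a median of 0.27, with 3 of 4 higher (percentile 95.25), but its member Ighm differed by -4.18. Ighm had means of 169 TPM in blood and 610 TPM in BM monocytes. Ms4a1, among the higher members, was at 1.73 and 0.892 TPM. The plasmacytoid dendritic cell list had one of 0.20, with 6 of 6 higher (percentile 95.35). The conventional dendritic cell list had one of 0.03, with 6 of 10 higher (percentile 74.09). Ly6C-low monocyte genes were higher in 17 of 21 cases, with a median of 0.80 (percentile 100), among them Treml4 at 2.58, Gngt2 at 2.36 and Csf1r at 2.11. Ly6c2 itself differed by -2.15, at means of 3325 and 6440 TPM, and varied widely over the blood cells, with an SD of 3.33 against 1.55. Immediate early and stress genes were higher in 14 of 23 cases at a median of 0.60, led by Dusp1 at 2.99, Atf3 at 2.51 and Nfkbia at 2.44. Of the other genes named by size, Tubb6 was higher by 4.17, Marcks by 3.40, Metrnl by 3.36, Tmem176b by 3.15 and Pla2g7 by 3.15. Pattern recognition and inflammatory signalling genes had a median of 0.27, with 22 of 33 higher and Il1b at 1.87. Myeloid transcription factors had a median of 0, with Maf at 2.90 and Klf4 at -1.56.

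All 35 G2 and M phase genes were lower in blood, with a median of -1.19 (percentile 0), and 29 of 30 S phase genes, with a median of -0.91 (percentile 0.05). As the log2 ratio of mean TPM these medians were -4.28 and -2.94. Ccnb2, a mitotic cyclin, had a mean of 162 TPM in BM monocytes and 0.179 TPM in blood monocytes. Stmn1, a microtubule regulator of dividing cells, differed by -3.74, the chromatin genes H2afv and Hmgn2 by -4.31 and -4.08, and the protease inhibitor gene Slpi by -4.29. Hk2, Abcg1 and Susd3 differed by -3.54, -3.38 and -3.36. Ly6i differed by -3.63 and Ly6g by -3.31, although reads of these genes can be shared with their paralogue Ly6c2. The neutrophil secondary granule and maturation list had a median of -0.85 (percentile 0.12), which was 0 with every member in the table counted.

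Nuclear oxidative phosphorylation genes were lower in blood in 72 of 76 cases, with a median of -1.15 (percentile 0) against -0.54 in the random lists, -0.34 as the log2 ratio of mean TPM and -0.64 in 32 pairs of blood and BM monocytes with like numbers of genes. Over its members, the median share of cells above 1 TPM was 68.4% in blood and 83.3% in bone marrow. Atp5g2 differed by -2.51. The 13 mitochondrially encoded genes had a median of 0.00. Glycolysis genes had a median of -0.54 (percentile 9.2), with Gpi1 at -2.38. Ribosomal proteins at -0.49 (percentile 59.4) did not stand apart from the random lists. Primary granule genes had a median of -0.35 (percentile 52.46), but -1.60 as the log2 ratio of mean TPM (percentile 0.3). Classical monocyte genes went both ways, with 14 of 27 higher, F13a1 at -2.93 and a median of 0.26 (percentile 100), which was -0.024 for members in at least 25% of cells. Type I interferon response genes had a median of 0.19 (percentile 99.98), lysosome and phagocytosis genes one of -0.20 (percentile 79.8), and migration and adhesion receptors one of 0.22. Ribosome biogenesis genes had a median of -0.04 and stem and multipotent progenitor genes one of 0. BM and blood monocytes share flow cell and lane, and 5 of the 20 genes named by size were also named from the log2 ratio of mean TPM.

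Blood monocytes and cMoP, the ends of the series, differed in many of the same gene groups, but this overlap is not independent evidence. Each gene's difference here is the sum of its differences for BM monocytes against cMoP and for blood against BM monocytes. The same cells were used again, so overlap with those comparisons arises by construction. Ccl6 was higher by 9.27 in blood, Apoe by 8.69, Ifi27l2a by 8.41, Wfdc17 by 8.10 and the lectin gene Clec4a3 by 7.97. Mpo differed by -13.04, Elane by -11.46, Prtn3 by -10.00, Ctsg by -9.75 and Stmn1 by -9.42, and Mpo and Elane were listed at 0 in all 38 blood cells. Ms4a3 differed by -8.04.

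S phase genes had a median of -5.26 and G2 and M phase genes one of -3.31, with 30 of 30 and 35 of 35 lower in blood. The second was -5.18 as the log2 ratio of mean TPM, and -1.95 among cells with 4500 to 6000 genes without libraries of high mitochondrial or low ribosomal share. Primary granule genes had a median of -6.60, with 9 of 10 lower, and ribosome biogenesis genes one of -3.51, with 30 of 30 lower. Classical monocyte genes had a median of 2.43, with 22 of 27 higher, Ly6C-low monocyte genes one of 1.42, with 17 of 21 higher, and immediate early and stress genes one of 1.47, with 18 of 23 higher. Type I interferon response genes had a median of 1.03, pattern recognition genes one of 1.14, and MHC class II presentation genes one of 0.54, which was 2.11 as the log2 ratio of mean TPM. Nuclear oxidative phosphorylation genes had a median of -2.54, which was -0.69 as the log2 ratio of mean TPM. The median over all measured genes was -0.58, and flow cell and lane cannot be told apart from this comparison.

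**Figure D3:**
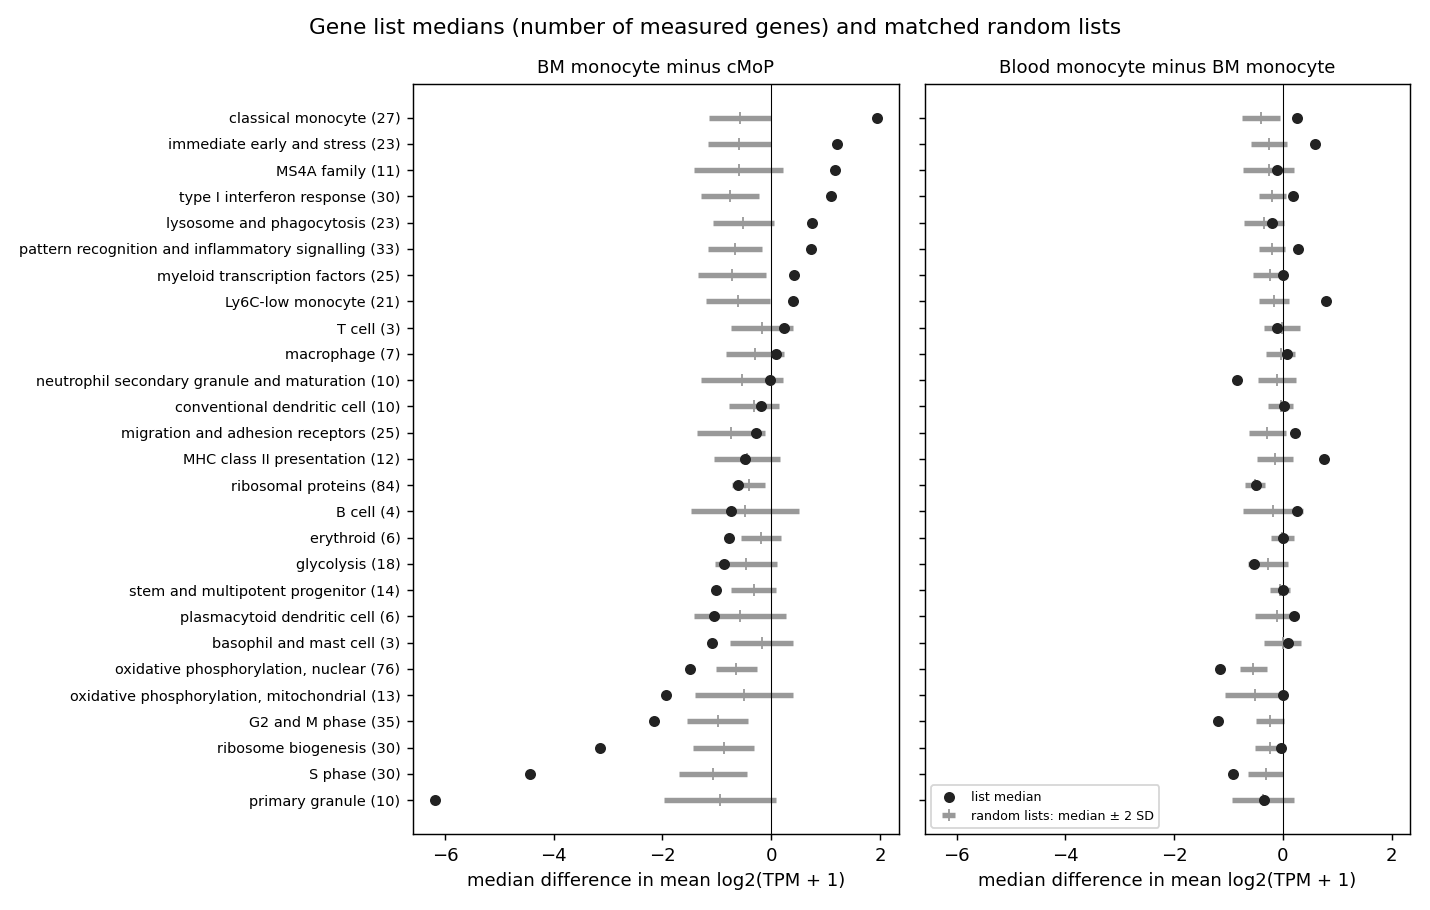
Median difference in mean log2(TPM + 1) of each gene list fixed before the data were examined, with the number of measured members in parentheses; grey bars are the median and 2 SD of 10000 random lists matched on mean expression. Primary granule, S phase and ribosome biogenesis lists lie lowest for BM monocytes against cMoP at -6.18, -4.44 and -3.14. Classical monocyte genes lie highest at 1.94. Nuclear oxidative phosphorylation at -1.49 turned to 0.79 among cells with 4500 to 6000 genes. It kept its sign in that range without libraries of high mitochondrial or low ribosomal share.

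Markers of other cell types were low or mixed. The B cell gene Cd79a and the T cell gene Cd3e, named outside the rule, were listed at 0 in every cell. In all, 5 of 11 B cell and 5 of 11 T cell list genes were. An exact 0 can be a failed estimate, so these zeros do not show absence. Ighm lay above 1 TPM in 100% of cMoP, 89.5% of BM monocytes and 68.4% of blood monocytes, at means of 598, 610 and 169 TPM. Cd79b lay above 1 TPM in 65.2% of cMoP and 10.5% of BM monocytes. The B cell list had a median of -0.73 for BM monocytes against cMoP, and 0.00 as the log2 ratio of mean TPM, and the T cell list one of 0.23. The NK cell list had 2 measured members, Klrk1 at -1.07 and Klrb1c at 0.16. The erythroid list had a median of -0.77, led by Hba-a2, which lay above 1 TPM in 43.9% of cMoP at a mean of 15.7 TPM. Mcpt8, a basophil protease gene, lay above 1 TPM in 18.2% of cMoP, and the basophil and mast cell list had a median of -1.08. The eosinophil list had 1 measured member, Ear2 at 2.24, and the megakaryocyte and platelet list 1, Itgb3 at -0.12. The macrophage list had a median of 0.10, which was -0.09 under median-ratio scaling. Conventional and plasmacytoid dendritic cell genes had medians of -0.18 and -1.05, and the first was 0.34 as the log2 ratio of mean TPM.

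The whole profiles separated the progenitor from the monocytes more than the monocytes from each other. Flow cell and lane separate the same groups, so this order cannot be told apart from them. The nearest group mean was their own for 65 of 66 cMoP (98.5%, 91.8 to 99.96%), 47 of 57 BM monocytes (82.5%, 70.1 to 91.3%) and 33 of 38 blood monocytes (86.8%, 71.9 to 95.6%). Of the other BM monocytes, 7 were nearest to blood monocytes and 3 to cMoP, and 5 blood monocytes were nearest to BM monocytes. The 1 cMoP nearest to blood monocytes had 40.98% of TPM in mitochondrial rows.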

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

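Of the gene list medians under the alternatives, 933 moved by less than 1 SD over cells of the list's mean, 59 by more and 1 that stood apart from random lists changed sign. For named genes these counts were 3461, 74 and, among differences of 1 or more, 11. That SD is wide for a median: 314 of the 993 moved by more than 1 SD of the random lists, and of 593 outside the middle 95% of these lists 36 fell inside. Counting every change of sign, also of values near 0, 65 of 993 list medians and 87 of 3546 differences changed sign. The sets of cells without high mitochondrial or low ribosomal shares, and those with 4500 to 6000 genes, were chosen after seeing the data. The planned range matched on genes per cell held no cell and was not run. The planned filter at 1000 genes removed 0 cells, so it says nothing. The counts above still include it, with 84 list medians and 357 differences of named genes that could not move. The shares that did not move are therefore overstated. No analysis paired by animal was possible because the labels number no animals, and no significance test between groups was run. TPM keeps no depth, so what depth limits could not be measured.

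At 10 TPM the Ms4a3 shares were 90.9% of cMoP, 0% of BM monocytes and 0% of blood monocytes, and median genes per cell 4477.5, 2747 and 2470; for any value above 0 they were 7881.5, 5697 and 5237. With a pseudocount of 0.1 the Ms4a3 difference was -11.17 for BM monocytes and -11.01 for blood monocytes against cMoP, primary granule medians -8.93 and -9.43, S phase -6.23 and ribosome biogenesis -4.49 (BM), and classical monocyte 3.72 (blood). With a pseudocount of 10 these were -5.10 and -5.09 for Ms4a3, -3.57 and -3.82, -2.57 and -1.81. A larger pseudocount shrinks differences from low values by construction.

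As the log2 ratio of mean TPM, BM monocytes against cMoP had S phase at -2.28, classical monocyte at 3.45, type I interferon response at 2.59 and Ighm turned to 0.029; blood against BM monocytes had S phase at -2.94 and G2 and M phase at -4.28; Dpp4 turned to 0.40 for blood monocytes against cMoP. The genes named by size kept 4 of 20, 5 of 20 and 4 of 10. Among cells with 4500 to 6000 genes, BM monocytes against cMoP had S phase at -2.71, ribosome biogenesis at -1.87, and turned signs for nuclear oxidative phosphorylation at 0.79, Fcnb at 0.32, Tpi1 at 0.32 and Ighm at 0.53. Blood monocytes against cMoP had classical monocyte genes at 3.62 there, and Ly6c2 turned to 0.31 and Dpp4 to 0.26; Cxcr4 turned to -0.024 for blood against BM monocytes. In that range without the high mitochondrial or low ribosomal libraries, nuclear oxidative phosphorylation was -1.42, as in the whole set in sign; Cxcr4 was -0.024, Dpp4 0.41 and Hk3 0.058. The cMoP nearest their own mean were 90.9% by Spearman correlation, and 100% without the 6 libraries with no flow cell and 100% without the high mitochondrial or low ribosomal ones. The cause was not tested for the other values that moved.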

Other observations

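The tests of cMoP RNA in BM monocytes, of a decline of all abundant genes and of pairs of cells were chosen after the results they concern were seen, as were the range of 4500 to 6000 genes and the 5 gene lists described first.

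Receptor and metabolic gene groups outside the fixed lists also differed between cMoP and BM monocytes. All 9 SIRP and paired immunoglobulin-like receptor genes were higher in BM monocytes, with a median of 4.77. Sirpb1c was listed at 0 in every cMoP and had a mean of 409 TPM in BM monocytes, and Pirb, an inhibitory receptor gene, was at 16.9 and 387 TPM. All 6 lectin genes of the Clec4a group and its neighbours were higher, with a median of 2.95, among them Clec4a1 at 4.27. All 10 serine and one-carbon synthesis genes were lower, with a median of -3.44, including Psat1 at -4.68 and Shmt1 at -4.06. All 15 mitochondrial chaperone and import genes were lower, with a median of -2.95, led by Hspd1 at -5.71 and Trap1 at -4.18. The 14 proteasome core genes were lower in BM monocytes than in cMoP at a median of -1.38, and lower in blood than in BM monocytes at -1.40. These lists were picked from these libraries, so their directions are not independent evidence.

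The 6 cMoP libraries without a flow cell in their label held more genes above 1 TPM than the other 60. If deeper sequencing of single cells were the cause, their spread in abundant genes would match that of other cMoP. The median SD over 292 genes with a mean above 500 TPM was 0.37 over the 6 libraries. The lowest of 1000 random sets of 6 other cMoP libraries was at 0.45, so this prediction was not met. Those others included the 11 libraries of high mitochondrial share. Without these, over 49 other libraries and 220 genes, a version chosen after, the values were 0.342 and 0.388. The bound assumed that depth leaves the spread of abundant genes unchanged and that the 6 share the profile of the others. The depth is unknown and the correlations below differ, so it does not decide on depth. RNA of several cells in each library stays open. It would bring each library closer to the mean of the others, and 0 of the 6 correlated better with it than the median of the others did. That bound assumed a shared profile, which the values do not show: the median correlation between 2 of the 6 was 0.803 and with the mean of the others 0.616, whereas it was 0.562 and 0.766 for the others. It was set aside for this reason after the result was seen. The narrow spread goes with pooled cells, but deeper sequencing and another run or protocol are open as well. Ms4a3 ranged from 159 to 568 TPM over the 6 and from 1.18 to 3221 TPM over the others. A range widens with the number of libraries, so these ranges decide nothing.

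In some BM monocytes Elane, Prtn3 and Ctsg exceeded 10 TPM while Ms4a3 was below that level in all 57. RNA or reads from cMoP would bring Mpo too, but mean Mpo was 1.18% of the 136 TPM that the Elane share predicts, which argues against it. 6 BM monocytes had both Elane and Prtn3 above 10 TPM, against 1.75 from the product of the shares. A subset of BM monocytes that keeps granule transcripts may be present, as a hypothesis. Other differences between cells would give such an excess too, so it does not single out that subset. The 3 BM monocytes nearest to the cMoP mean were among these 6. They had Elane at 438, 1335 and 215 TPM, Prtn3 at 476, 398 and 468 TPM, and Ms4a3 at 0. Top2a, a gene of dividing cells, was at 1248.5, 370 and 442 TPM. The last of these cells held Mpo at 89.7 TPM, nearly all of the Mpo in the group. Dividing cells between the 2 stages, or other sorted cell types with these transcripts, stay open.

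Nuclear oxidative phosphorylation genes were lower in blood than in BM monocytes. A decline of all abundant genes alike would put the list in the middle of the matched random lists, but its percentile was 0. In these libraries the list thus lay below genes of like expression. This bound was chosen after the percentile was seen, and the percentile is not a test, so it does not decide the cause. The random lists had a median of -0.54 themselves, so that part of the -1.15 is shared with genes of like expression. Fewer genes detected per library in blood stays open. In cells with 4500 to 6000 genes the median was -1.08, but that range leaves a gap of 362.5 genes between the groups, against 399.5 over all cells, so it decides nothing. In 32 pairs of 1 blood and 1 BM monocyte within 100 genes of each other it was -0.64. The 95% bootstrap range over pairs, -0.97 to -0.25, covers the spread between cells only. That range spans the bound of -0.57, so fewer genes detected cannot be told apart from a lower content of these transcripts. The ratio of mean TPM was smaller at -0.34, and the median share of cells above 1 TPM was 68.4% in blood and 83.3% in bone marrow. Proteasome core genes were lower too. Separate capture or handling of blood and marrow cells, which the labels do not describe, also stays open.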
